A study of Homo sapiens with 5 samples.

How the data were processed

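TET1 (WT) and DNMT3B (WT and TKO) were immunoprecipitated from HUES8 cells, 1 library per group, with 1 input library per genotype. Per the labels' protocols, cells were fixed and frozen, and a service company did the immunoprecipitation and made the libraries. Per the submitters' processing notes, Bowtie and the hg19 build were used; the Bowtie version is not given in the sources used here. The deposited data are 3 peak lists, 1 per ChIP library, each named as a comparison with input. The peak names in them carry the word MACS, a peak caller; its version and threshold are not given in the sources used here. Each peak has a position and a score, which the authors deposited without a header to define it, so it is treated as a score with no stated unit. The lowest scores are 50.01 for TET1 and 50 for both DNMT3B lists. Scores were used to rank, filter or describe peaks within a list. In 1 test, peaks with high scores in one DNMT3B list were sorted by whether their best partner scored under 100 in its own list; scores have not been shown to be on the same scale in both lists, so that test is weak. Since calling was done per library against input, a region absent from a list was below the caller's threshold or left out by the caller, which the lists do not tell apart.

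The number of peaks in each list, their widths and covered length were computed from the positions. Peaks were numbered without gaps in each list and did not overlap within a list. The peaks of 2 lists were counted as overlapping from 1 bp. TET1 peaks were counted as gained where they touched a TKO but no WT DNMT3B peak, and as lost in the reverse case. Chance overlap was described with 1000 random placements of the peaks on their own chromosome, between the first and last peak of any list, unsequenced gaps included. Shares carry exact Clopper-Pearson intervals at 95%. Reads are not counted in these files, so their depth is unknown, and the number of peaks sets the width of the intervals. Positions are given from 1, in hg19. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. The overlap step was tested on simulated data: over 200 random pairs of lists it made 0 errors against a direct count, and with 199 gains planted at the 19935 TET1 peaks in a copy of the WT DNMT3B list, it counted 208 gains, since a planted peak of 1 kb can also reach a neighbouring TET1 peak.

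Overlaps, placements on the chromosome, the 5 bins of TET1 score, the rule for named regions and most alternatives were fixed before the data were examined. The following were chosen after seeing the data: placements 10 to 50 kb away in either direction, coverage at TET1 midpoints against flanks 10 to 20 kb away (positions every 250 bp), the last 5 Mb of each chromosome, 1 Mb windows, the midpoint count, and the tests of peaks without a partner and of peak edges. The intervals of the midpoint ratios came from 2000 resamples of 5 Mb blocks. The last 5 Mb was taken from the end of the last peak on a chromosome, and the sequence of a chromosome as the span of its peaks less its largest gap.

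Alternatives were an overlap of at least 50% of the shorter peak, the higher-scoring 50% of each list, DNMT3B lists of equal length, peaks of 500 bp around each midpoint, peaks within 1 kb joined, and 10 score bins. Added later were DNMT3B lists of equal covered length, leaving out peaks with scores of 300 or more that lacked a partner, and leaving out 5 Mb at chromosome ends and around the largest gap. The reference table of genes used here is of the GRCh38.p14 assembly and the peaks are on hg19. On 9 chromosomes, peaks end over 0.5 Mb past the last gene of that table. Peaks were therefore not placed on genes, and the planned comparisons of promoters, exons and introns, fixed gene lists and CpG content are not analysed here. The rule for named genes was applied to regions in place of genes: the 10 highest-scoring peaks of each list, the 10 gained TET1 peaks with the highest TKO DNMT3B score and the 5 lost ones with the highest WT DNMT3B score, of which the text names examples. The peaks named from outside this rule, the longest ones and the highest-scoring ones with no partner within 1 kb, were chosen after their values were seen. The TET1 peak on an extra reference sequence was left out of the random placements, midpoint ratios and chromosome comparisons.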

Results

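Binding of TET1 and DNMT3B was measured by ChIP-seq in HUES8 cells, an established human embryonic stem cell line grown on irradiated mouse fibroblast feeder cells. TET1, TET2 and TET3 are enzymes that oxidise methylated cytosine, and DNMT3B is a methyltransferase that adds methyl groups to unmethylated cytosine. TET1 was profiled in wild-type (WT) cells. DNMT3B was profiled in WT cells and in cells with inactivating mutations in TET1, TET2 and TET3 (triple knockout, TKO). Each of these 3 groups had 1 ChIP library, and each genotype had 1 input library, giving 5 libraries. With no replicates, the spread between cultures is unknown and no p-value is given for the genotype. The loss of the TET genes themselves cannot be checked in peak lists. The read depth of the libraries is unknown, since peak lists hold no read counts. Shares of peaks carry exact (Clopper-Pearson) 95% binomial intervals, which cover counting error only. They treat peaks as independent, although many DNMT3B peaks lay close together. Joining peaks within 1 kb left 24561 of 39391 WT and 30825 of 50916 TKO DNMT3B peaks. The binomial intervals are therefore too narrow. Peaks are reported by their hg19 position, and scores are those the authors deposited with their peaks.

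TET1 in WT cells gave 19935 peaks that covered 16.7 Mb, with a median width of 745 bp. The DNMT3B lists covered far more of the genome, in longer stretches. The WT DNMT3B list held 39391 peaks over 81.9 Mb, with a median width of 1338 bp, and the TKO DNMT3B list held 50916 peaks over 90.9 Mb, with a median width of 1131 bp. The TKO list thus had 1.29 times as many peaks and 1.11 times the covered length of the WT list. Peaks wider than 5 kb made up 7.67% of the WT and 5.62% of the TKO DNMT3B peaks, against 0.0652% of the TET1 peaks. The longest DNMT3B peak in WT cells spanned 35975 bp on chromosome 7 (1507475 to 1543449), and the longest in TKO cells spanned 52592 bp on chromosome 3 (126703636 to 126756227). The size of a peak list moves with sequencing depth and with the caller's threshold. The differences in size between the DNMT3B lists, and between the TET1 and DNMT3B lists, therefore have no test here.

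DNMT3B peaks were concentrated towards the ends of the long arms of most chromosomes, in both genotypes. Peaks at the ends of the short arms were not counted, so the concentration was not shown to be particular to the long arms. Over the autosomes and X, the last 5 Mb of each chromosome held 21.1% of the WT DNMT3B peaks (interval 20.7% to 21.5%) and 20.1% of the TKO DNMT3B peaks (19.8% to 20.5%), although these stretches made up 4.08% of the sequence. The same stretches held 6.63% of the TET1 peaks (6.29% to 6.99%). The share of WT DNMT3B peaks exceeded that of TET1 peaks on 20 of 23 chromosomes. On chromosome 21 the last 5 Mb held 84.7% of the WT and 83.3% of the TKO DNMT3B peaks, and on chromosome 13 it held 76.0% and 68.6%. The exceptions were chromosomes 1, 4 and 19, where the WT DNMT3B shares were 0.767%, 1.42% and 5.08% and the TET1 shares 2.06%, 3.33% and 9.79%. By density, chromosomes 22, 19 and 17 had the most WT DNMT3B peaks per Mb (69.6, 52.1 and 40.7), and X had the fewest (2.99). TET1 peaks were also densest on chromosome 19, at 25.04 per Mb, followed by chromosome 17 at 15.3 per Mb.

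**Figure D1:**
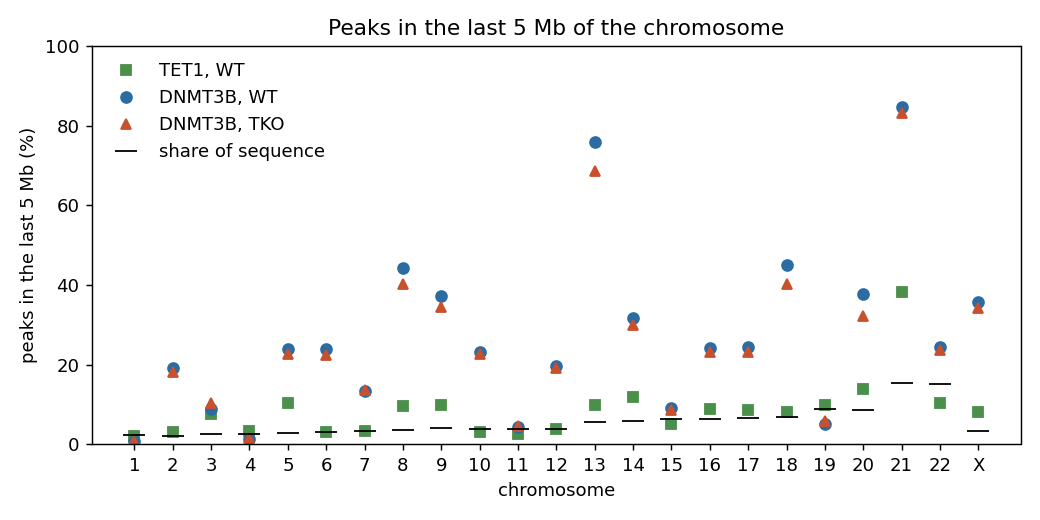
Share of the peaks of each chromosome (y axis, %) that lay in its last 5 Mb, for each autosome and X (x axis), with 1 symbol per peak list and a dash for the share of the chromosome's sequence. The DNMT3B symbols of both genotypes lie above the TET1 symbol on 20 of 23 chromosomes, with the highest WT DNMT3B shares on chromosomes 21 (84.7%) and 13 (76.0%).

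The comparison of DNMT3B between genotypes asks where the methyltransferase sits once all 3 TET enzymes are lost. Most of its territory was common to both genotypes. Of the WT DNMT3B peaks, 76.7% (76.2% to 77.1%) touched a TKO DNMT3B peak by at least 1 bp. The mean was 8.49% when the WT peaks were placed at random on their chromosomes 1000 times. That mean is a low baseline, since the placements ignored the clustering of DNMT3B peaks and could fall in unsequenced gaps. No nearby placements were made for DNMT3B peaks. From the other side, 62.6% (62.2% to 63.0%) of the TKO peaks touched a WT peak. The gap between these shares followed the lengths of the lists: with the TKO list shortened by score to the length of the WT list, they were 70.4% and 72.0%. The common stretches summed to 66.1 Mb, which was 80.7% of the WT and 72.8% of the TKO covered length. Each of the 23 chromosomes compared had more DNMT3B peaks in TKO than in WT cells, from 1.23 times as many on chromosome 17 to 1.43 times on chromosome 18. The surplus was proportionally smaller where DNMT3B was dense. In the 435 densest 1 Mb windows the TKO list had 1.24 times as many peaks as the WT list. In the 435 sparsest windows with any DNMT3B peak it had 2.23 times as many, from 325 TKO and 146 WT peaks.

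Peaks found in 1 genotype were mostly weak and narrow. The 19032 TKO-only peaks had a median width of 770 bp and a median score of 68.9, whereas TKO peaks with a WT partner had a median width of 1576 bp and a median score of 156.6. The 9196 WT-only peaks had a median width of 791 bp and a median score of 63.9, against 1654 bp and 128.9 for WT peaks with a TKO partner. Both TKO-only peaks (14.8%, 14.3% to 15.3%) and WT-only peaks (14.5%, 13.8% to 15.2%) lay less often in the last 5 Mb of a chromosome than TKO peaks with a WT partner (23.3%, 22.8% to 23.7%). Of the TKO-only peaks, 33.8% lay over 10 kb from any WT DNMT3B peak, and of the WT-only peaks, 23.5% lay over 10 kb from any TKO DNMT3B peak. With rising score, the share without a partner fell from 70.8% to 1.57% in the TKO list and from 53.7% to 0.202% in the WT list, for scores of 50 to 60 and of 300 to 500. Above that it fell no further in the WT list, where 3 of 289 peaks with scores of 2000 or more (1.04%, 0.215% to 3.004%) had no partner. In the TKO list 8 of 696 such peaks (1.15%, 0.498% to 2.25%) had none.

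**Figure D2:**
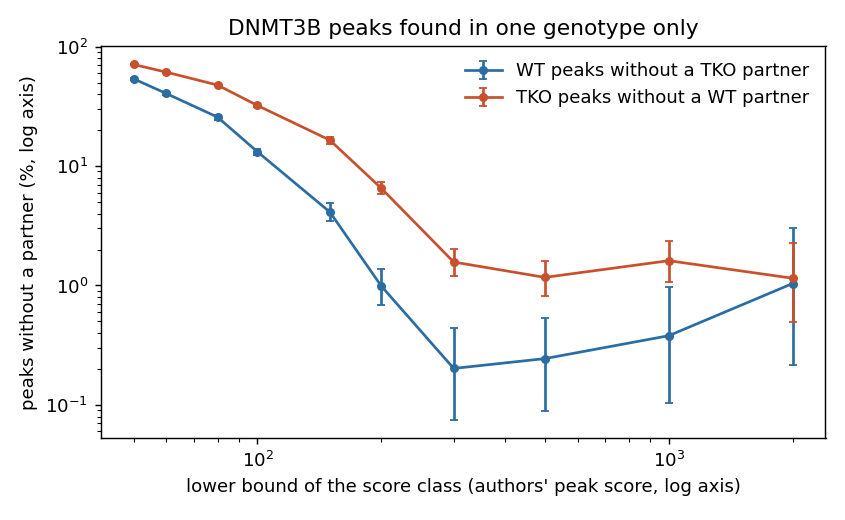
Share of DNMT3B peaks with no overlapping peak in the other genotype (y axis, %, log scale) by the authors' peak score (x axis, lower bound of each score class, log scale), for the WT list and the TKO list, with exact 95% binomial intervals as bars. Both curves fall up to a score of 300 (0.202% in WT and 1.57% in TKO) and then level off or rise.

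The main question of the design was whether DNMT3B appears at TET1 sites when the TET enzymes are lost. TET1 peaks rarely carried DNMT3B in either genotype: 950 of 19935 TET1 peaks (4.77%, 4.47% to 5.07%) touched a DNMT3B peak in WT cells and 1165 (5.84%, 5.52% to 6.18%) in TKO cells. DNMT3B was present at 763 TET1 peaks in both genotypes, was gained in TKO at 402 and was lost at 187. The TKO count was 1.23 times the WT count. At 93.2% of TET1 peaks there was no DNMT3B peak in either genotype.

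TET1 peaks lay in neighbourhoods rich in DNMT3B but on positions poor in it. Placed at random on their own chromosomes, TET1 peaks met WT DNMT3B in 4.90% of cases on average (95% range of 1000 placements, 4.63% to 5.20%) and TKO DNMT3B in 5.61% (5.29% to 5.94%), so the observed shares lay inside both ranges. These placements could fall in unsequenced gaps, which lowers both ranges by an amount that was not measured. With gaps left out, the observed WT share, near the low end of its range, might therefore lie below it. Moved by 10 to 50 kb, TET1 peaks met WT DNMT3B in 10.96% (10.6% to 11.3%) and TKO DNMT3B in 12.4% (12.0% to 12.8%), above the observed share in each of the 1000 placements. DNMT3B peaks covered 3.35% of TET1 midpoints in WT cells, against 8.87% of positions 10 to 20 kb away, a ratio of 0.378 (block bootstrap interval 0.333 to 0.431). In TKO cells they covered 4.29% of midpoints and 9.70% of the flanks, a ratio of 0.443 (0.393 to 0.499). The dip was therefore present in both genotypes.

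**Figure D3:**
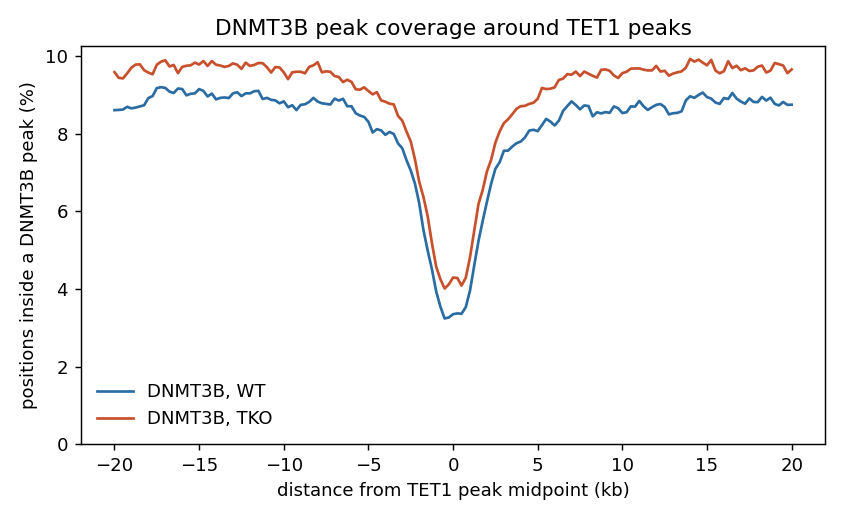
Share of positions inside a DNMT3B peak (y axis, %) by distance from the midpoint of TET1 peaks (x axis, kb, out to 20 kb on either side), over 19934 TET1 peaks, for WT and TKO cells. Both lines drop at the midpoint, to 3.35% in WT and 4.29% in TKO, from flanks of 8.87% and 9.70%.

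The dip was shallower in TKO cells. Coverage by DNMT3B was 1.28 times as high in TKO as in WT cells at TET1 midpoints (1.21 to 1.37) and 1.09 times as high in the flanks (1.08 to 1.11), and the ratio of these ratios was 1.17 (1.11 to 1.25). These intervals come from resampling stretches of the genome and do not cover the spread between cultures. Positions with the same local DNMT3B density as TET1 midpoints were not compared, and the TKO surplus in number of peaks was larger where DNMT3B was sparse. The TKO to WT ratio of overlapped TET1 peaks, 1.23, was reached in none of the 1000 placements on the same chromosome (mean 1.14) or of the 1000 placements nearby (mean 1.13). The balance of gains and losses differed less from chance: gains made up 68.3% (64.3% to 72.0%) of the TET1 peaks that changed, against 65.8% (62.8% to 69.0%) for TET1 peaks moved by 10 to 50 kb. When the TKO list was restricted by score to the covered length of the WT list, gains were 308 and losses 231, or 57.1% of the changes (52.8% to 61.4%), and moved peaks gave 51.1% (47.5% to 54.6%). Of TET1 peaks without WT DNMT3B, 2.12% gained it in TKO, a share above that of peaks placed on the same chromosome (1.57%, 1.39% to 1.76%) and below that of peaks moved by 10 to 50 kb (3.31%, 3.06% to 3.58%). Of TET1 peaks with WT DNMT3B, 19.7% lost it, a share above both placements (16.1%, 13.9% to 18.5%, and 14.0%, 12.6% to 15.4%). With the higher-scoring 50% of each list, the ratio of ratios was 1.103 and its interval reached 1.

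TET1 peaks with high scores carried DNMT3B less often. In 5 equal bins of TET1 score, the share with WT DNMT3B was 5.96% (5.25% to 6.75%) in the lowest bin and 3.34% (2.80% to 3.94%) in the highest, and with TKO DNMT3B 7.37% (6.58% to 8.22%) and 3.89% (3.31% to 4.53%). Gains among TET1 peaks without WT DNMT3B were 2.59% (2.10% to 3.14%), 2.38%, 2.68%, 1.62% and 1.35% (1.01% to 1.77%) from the lowest bin to the highest. Losses did not fall in the same way, at 17.2% (12.7% to 22.6%) in the lowest and 22.6% (15.8% to 30.6%) in the highest bin, with overlapping intervals. None of the 10 highest-scoring TET1 peaks on the chromosomes touched a DNMT3B peak in either genotype. That adds little, given the low shares in the highest bin. The first of these 10 peaks lay on chromosome 20 (34329443 to 34330880, score 2951.1). Others lay on chromosome 17 (37616989 to 37618357, score 2089.91), chromosome 20 (30945417 to 30946405, score 2086.02) and chromosome 19 (49998730 to 50000028, score 2061.8). The intervals of gain in the end bins overlapped under 3 alternatives: the higher-scoring 50% of each list (1.29%, 0.839% to 1.90%, and 0.721%, 0.395% to 1.21%), 10 score bins (2.72%, 2.03% to 3.56%, and 1.51%, 1.01% to 2.16%), and leaving out chromosome ends and gap edges (2.11%, 1.63% to 2.69%, and 1.23%, 0.874% to 1.69%).

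The highest-scoring DNMT3B peaks were long and mostly common to both genotypes. In WT cells the first was on chromosome 17 (75481254 to 75490296, score 3233.06), then on chromosome 5 (1073329 to 1081139, score 3226.07) and chromosome 19 (54962905 to 54972882, score 3221.6). In TKO cells the first were on chromosome 19 (15348451 to 15353911, score 3230.05) and on chromosome 16 (15220554 to 15225620, score 3219.44, and 22332656 to 22341035, score 3191.8). Of the 10 highest in WT cells, 9 touched a TKO peak, and of the 10 highest in TKO cells, 10 touched a WT peak. A score of exactly 3100 recurred, at 62 WT and 202 TKO peaks, so peaks with this score have no order among them. Only 13 WT and 24 TKO peaks scored above it. Whether 3100 is a limit of the score is not stated, so the peaks ranked highest by score need not be the strongest. The WT peak among the 10 with no TKO partner lay on chromosome 16 (1256941 to 1274008, score 3202.28), inside a stretch of 26402 bp with no TKO peak. Among TKO-only peaks over 1 kb from any WT peak, 2 shared the highest score, 3100. They lay on chromosome 12 (57585701 to 57594160), inside a stretch of 25361 bp with no WT peak, and on chromosome 19 (878940 to 889100), inside a stretch of 17746 bp with none.

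**Figure D4:**
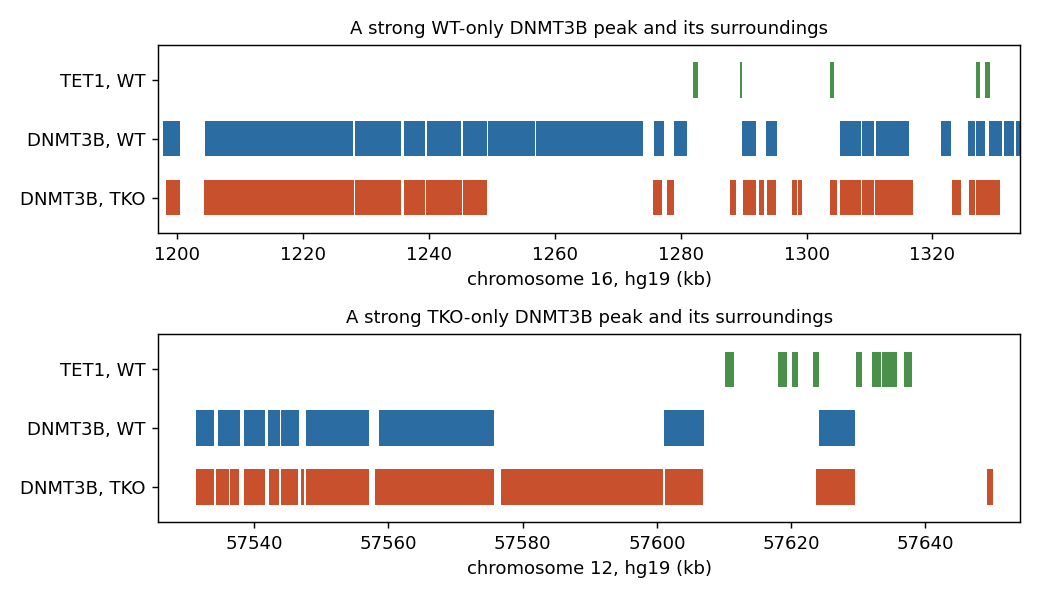
Peaks of the 3 lists (rows, bars to scale) along hg19 position (x axis, kb) around a strong DNMT3B peak over 1 kb from any peak of the other genotype, on chromosome 16 for WT (top, score 3202.28) and chromosome 12 for TKO (bottom, score 3100, which a peak on chromosome 19 shares), with 60 kb shown on either side. In the upper panel the TKO list is empty from 1249196 to 1275599, and in the lower panel the WT list is empty from 57575745 to 57601107, while peaks next to these stretches are present in both genotypes.

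TET1 peaks that gained DNMT3B are named here by the score of the TKO peak that met them. Of the 10 highest, 9 were met by a TKO peak that itself touched a WT DNMT3B peak, a share that follows from the choice by score, since 1.48% of all TKO peaks with scores of 1000 or more lacked a WT partner. The TET1 peak on chromosome 16 at 698751 to 699632 shared 93 bp with a TKO peak of 11388 bp, and the nearest WT DNMT3B peak lay 286 bp away. The TET1 peak on chromosome 19 at 1020210 to 1020886 shared 35 bp with a TKO peak of 10793 bp, with WT DNMT3B 6 bp away. The exception was chromosome 17, 19035102 to 19036498, where a TKO peak of 8744 bp (score 1163.16) covered the whole TET1 peak and the nearest WT DNMT3B peak lay 9889 bp away. All 5 highest-scoring losses came from a WT peak that also touched a TKO peak, such as chromosome 17, 19280775 to 19282027, with 1 bp shared. The median length shared by the TET1 and DNMT3B peaks was 524 bp over all 402 gains and 413 bp over all 187 losses. Of the 402 gains, 107 (26.6%, 22.4% to 31.2%) came from a TKO peak that touched a WT peak elsewhere, and 82 of 187 losses (43.9%, 36.6% to 51.3%) from a WT peak that touched a TKO peak elsewhere. The median TKO score at gains was 91.4. Counted at TET1 midpoints, which leaves out contacts that stop short of the midpoint, there were 330 gains and 142 losses, and gains made up 69.9% of the changes (65.6% to 74.0%).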

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

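The TET1 list held 1 peak on an extra reference sequence named ribosomal. It is among the 19935 TET1 peaks counted for overlap and score bins, but not in the placements, midpoint ratios or chromosome comparisons. It spanned positions 3584 to 7304 of that sequence and had a score of 545.53, higher than 99.5% of the TET1 peaks. The DNMT3B lists held 0 peaks there. It drew attention as a signal outside the chromosomes, and no explanation for it was tested.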

How the results depend on the processing

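Of 99 values recomputed for 15 results, 47 moved outside the interval of the reported value and 42 stayed within it. The remaining 10 were identical, because the alternative did not touch them. Binomial intervals treat peaks as independent and are too narrow, so with wider ones fewer values might count as moved. The alternatives with equal covered length, without strong unpartnered peaks, without chromosome ends and with nearby placements were chosen after seeing the data. Except where a filter by construction removes peaks, the cause was not tested. Values below are in the order WT, TKO where 2 are given. For DNMT3B peaks shared with the other genotype they were 74.4% and 60.2% with an overlap of 50% of the shorter peak, 83.1% and 68.1% with the higher-scoring 50% of peaks, 70.4% and 72.0% with lists of equal length, 70.1% and 72.3% with equal covered length, 55.5% and 43.04% with 500 bp peaks, 73.4% and 57.6% with joined peaks, and 72.4% and 58.2% without chromosome ends and gap edges. The order of the genotypes thus turned once lists had equal length.

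TET1 peaks with DNMT3B were 3.40% and 4.40% with 50% of the shorter peak, 2.71% and 3.20% with higher-scoring peaks, 1.50% and 2.22% with 500 bp peaks, and 3.19% and 4.12% without chromosome ends. The TKO share was 5.18% with equal length and 5.15% with equal covered length. Relative to placed peaks they were 0.435 and 0.472 with placements 10 to 50 kb away, against 0.973 and 1.04 on the whole chromosome, so the TKO value went from just above 1, with a range that spanned 1, to below it. Midpoints over flanks gave 0.228 and 0.251 with higher-scoring peaks and 0.492 and 0.591 with 500 bp peaks; the TKO to WT ratio of these was 1.103 with higher-scoring peaks. Gains among changed TET1 peaks were 57.6% with equal length and 57.1% with equal covered length.

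Gains in the lowest and highest TET1 score bins were 1.29% and 0.721% with higher-scoring peaks and 2.00% and 0.986% with equal covered length. The lowest was 2.00% with equal length, and the highest was 0.921% with 50% of the shorter peak and 0.480% with 500 bp peaks. DNMT3B peaks in the last 5 Mb were 25.1% and 24.3% with higher-scoring peaks and 18.4% and 16.9% with joined peaks, and in TKO 21.5% with equal length and 21.6% with equal covered length. The TET1 share there was 6.21% with higher-scoring peaks.

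Not run, for want of an hg19 gene annotation or genome here, were the alternatives on promoter windows, start sites, CpG bins, random gene lists and placement near promoters. No paired analysis was possible because each group had 1 library, and for the same reason no library was left out. Depth is unknown, and weak peaks near the score threshold limit the comparison of lists.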

Other observations

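The tests of list length, of turnover, of a genotype effect on strong peaks and of TET1 contact at a fixed width were chosen after the results were seen. TET1 peaks with DNMT3B in both genotypes lay in the last 5 Mb of a chromosome in 23.2% of cases (20.3% to 26.4%, 177 of 762 on the autosomes and X), a share close to the 23.3% of TKO DNMT3B peaks with a WT partner. The TET1 peaks that gained DNMT3B did so in 12.0% (8.98% to 15.6%), against 14.8% of TKO-only DNMT3B peaks. The highest-scoring TET1 peaks with DNMT3B in both genotypes lay on chromosome X (114977392 to 114982063, score 452.92) and chromosome 5 (70070403 to 70077238, score 403.64). TKO-only DNMT3B peaks touched TET1 in 1.61% of cases (1.43% to 1.80%) and TKO peaks with a WT partner in 2.57% (2.40% to 2.75%), but the latter were wider. With each DNMT3B peak as 500 bp around its midpoint, the shares were 1.25% (1.098% to 1.42%) and 1.07% (0.957% to 1.19%), with overlapping intervals. WT-only peaks, also weak and narrow, touched TET1 in 1.20% of cases (0.984% to 1.44%), and at 500 bp in 0.903% (0.720% to 1.12%). Both shares were lower than those of TKO-only peaks, with intervals that overlapped slightly.

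DNMT3B coverage rose more in TKO at TET1 midpoints than in the flanks. The midpoints were sparser in DNMT3B than the flanks. Across 1 Mb windows, the TKO surplus in number of peaks was also larger where DNMT3B was sparse. The TKO list had 2.23 times as many peaks in the sparsest windows and 1.24 times in the densest. The windows compare numbers of peaks and the midpoints compare coverage, which need not rise alike. Over the whole lists the TKO to WT ratios of these were 1.29 and 1.11. No positions matched to the midpoints in local DNMT3B density were compared. The rise was therefore not shown to be particular to TET1 sites. A longer TKO list as the whole cause would bring the ratio of ratios near 1 at equal covered length, where it was 1.13 (1.06 to 1.21). Leaving out strong peaks missing from one list gave 1.17 (1.105 to 1.24). That step removed only 19 of 39391 WT and 129 of 50916 TKO peaks, so it says little about a cause. More turnover of DNMT3B calls in both directions stays open. Losses at TET1 peaks exceeded those of nearby placements (24.3% against 18.0% at equal covered length). The share of gains among changes lay inside the nearby range on the deposited lists (68.3%, range 62.8% to 69.0%). Turnover alone would leave that share inside the nearby range at equal covered length too. There it was 57.1%, above the nearby range (47.5% to 54.6%). It was reached by 0 of 1000 nearby placements and by 5 of 1000 on the chromosome. Its counting interval of 52.8% to 61.4% overlapped both ranges, so these values did not settle it. The loss of the TET genes may underlie the rise, but with 1 library per genotype a difference between the DNMT3B libraries other than the genotype cannot be told apart from it.

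Some strong DNMT3B peaks of one genotype had no partner in the other, as in the map of the regions on chromosomes 16 and 12. If the caller left out wide strong regions, absence would outnumber weakening; of peaks with scores of 500 or more, 84 had no partner (13 WT, 71 TKO) and 55 a best partner with a score under 100, but at scores of 300 or more the order turned, with 148 and 316. An omission by the caller may thus account for some of the strongest cases but stays open, since scores of the lists need not be on one scale. A change of DNMT3B occupancy with the loss of the TET genes also stays open, with 1 library per genotype.

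A hypothesis that DNMT3B domains extend towards TET1 sites in TKO was tested on the edges of 2384 pairs of WT and TKO peaks within 5 kb of a TET1 peak that had no WT DNMT3B. The median outward shift from WT to TKO was -0.5 bp at the edge facing TET1 and -5 bp at the far edge. The median difference between them was 4.5 bp, with an interval of -4 to 22 bp, so the typical pair showed no detectable extension. A median cannot show extension at a small part of the pairs, so the hypothesis stays open there. Of the 402 gains, 107 came from a TKO peak that touched a WT peak elsewhere. In the reverse direction, 82 of the 187 losses came from a WT peak that touched a TKO peak elsewhere.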
